A study of Mus musculus with 6 samples.

How the data were processed

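RNA of Raw264.7 cells, a mouse macrophage line, was profiled by RNA sequencing in 6 samples, 3 from cells on titanate nanowires made by alkaline heat treatment of titanium (TH, the control surface) and 3 from cells on titanium carrying a calcium phosphate nanowire coating (THCaP). Per the labels' protocols, cells attached for 12 h, received 1 µg/mL of lipopolysaccharide (LPS, a bacterial cell wall component that activates macrophages) for 2 h and were cultured for 1 d. RNA was extracted with TRIzol and libraries were made with the VAHTS Universal V6 kit. The group and replicate number of each library came from its label.

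The deposited counts are whole numbers of reads per gene symbol, not normalised. Per the submitters' processing notes, fastp, HISAT2 and HTSeq were used with genome build mm10. Their versions, the gene annotation and the strand setting of the counting are not given in the sources used here, so reads of a gene and of an overlapping or antisense gene are not separable here. Near-identical family members (Mt1 and Mt2, Ccl3 and Ccl4, Ifi44 and Ifi44l, H2-K1 and H2-D1, ribosomal protein genes with processed copies) may share or lose reads. The deposited FPKM values (fragments scaled by gene length and library total) were computed by the authors from these counts: for the 11923 genes with at least 10 counts in a library, FPKM and count gave a gene length that was whole within 0.01 bases for 100% of genes. FPKM therefore carry no information beyond the counts, the library total and the gene length. They were used only in alternatives and as the source of the gene lengths used here.

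The table holds 16171 symbols, of which 16050 matched the mouse gene tables used here and 121 did not, 97 of these starting with LOC. Library totals ran from 28000099 to 30317108 counts, so 3 counts, the upper limit that a count of 0 allows, are at most 0.107 CPM (counts scaled by the library total) in any library. That limit covers counting error only. Positions of named genes came from GENCODE vM21 on GRCm38, the assembly that mm10 denotes.

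Counts were analysed in R 4.3.3 with edgeR 4.0.16: filterByExpr (minimum count 10, minimum total 15) kept 11480 genes, TMM factors scaled the libraries, and a robust quasi-likelihood F test compared THCaP with TH over all 6 libraries with no covariate. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. Log2 fold changes are THCaP over TH. Their standard error (SE) is the absolute log2 fold change divided by the square root of the F statistic. Group values are means of TMM-scaled CPM ± SD over 3 libraries. All p-values measure the spread between these samples only, because the labels do not say whether the libraries of a group came from separate cultures. For a single value compared between 3 and 3 libraries the smallest two-sided exact permutation p is 0.1.

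Before the data were examined, 31 gene lists were fixed, and 26 with at least 5 tested genes entered camera (limma 3.58.1). Camera asks whether the genes of a list move relative to all other tested genes. It was run with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the 26 lists. Camera was repeated with a correlation estimated for each list. Fry, run beside it, tests whether the genes of a list move on balance in one direction (its mixed p, in either direction) and does not compare a list with other genes. The lists for mitochondrially encoded genes and for markers of stromal, endothelial, lymphoid and neutrophil cells had too few tested genes.

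The naming rule, also fixed before the data were examined, took the 12 genes with the largest increase and the 12 with the largest decrease among called genes with a mean of at least 10 CPM and no overlap between the groups' libraries, leaving out unnamed gene models and pseudogenes. It added 18 macrophage and bone-related genes in every case, of which 13 passed the filter, and up to 4 called members of each list with at least 5 CPM, those with the largest change (up to 2 members with the highest expression where none was called). The rule gave 118 genes, some of which are not reported here. Lists share members, so a gene can stand under several lists.

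Libraries of a group were compared by a chi-square test over genes with at least 10 counts in the pair. Alternatives fixed before the data were examined were DESeq2 1.42.0, limma-voom, RLE factors, library totals without a composition factor, no filter, a filter of 5 CPM in at least 3 libraries, the replicate number as a block and each library left out in turn. The others were limma on log2(FPKM + 1) and log2(FPKM + 0.1) of genes with a mean FPKM of at least 1, the former also without a filter, a fold change tested against 1.2, an estimated correlation, fry, and lists without shared genes. Added after seeing the data were offsets that remove each library's smooth trend on GC content and gene length (mgcv 1.9.3, 97.4% of tested genes), and the omission of the libraries farthest from their groups in the principal components, TH replicate 1 and THCaP replicate 2.

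The procedures were tested on simulated counts drawn for the comparison of THCaP with TH from the real means, library sizes and dispersions. With 11422 genes in the step and 50 changed genes per fold size, edgeR recovered 94% of genes changed 3-fold, 86% at 2-fold, 80% at 1.5-fold and 26% at 1.3-fold, with 6.54% false calls. Camera called the list holding the simulated changes and 0 of the 25 others. Those simulated genes varied independently of each other, which the real ones did not. With nothing changed, edgeR called 0 of 11404 genes.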

Results

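Raw264.7 cells, a line of mouse macrophages, were cultured on titanium with titanate nanowires (TH) or with a calcium phosphate nanowire coating (THCaP). They were exposed to 1 µg/mL LPS for 2 h and cultured for 1 d. All samples received LPS, so a difference between the surfaces cannot be assigned to the LPS response or to expression without LPS. The comparison asks how gene expression of these macrophages differs between the surfaces. Each surface was represented by 3 RNA-seq libraries. Total counts were 30317108, 28198285 and 28647240 for TH replicates 1, 2 and 3 and 28000099, 29453473 and 28771147 for THCaP replicates 1, 2 and 3. Of 16171 genes in the table, 11480 were expressed highly enough to be tested, and the 10 most abundant genes took 6.02% to 7.17% of the counts of a library. Libraries of a group differed by more than sampling noise in every pair, so none was taken as a repeat deposit of another, which does not show separate cultures. The chi-square per degree of freedom was 3.84 between TH replicates 2 and 3 and 12.5 to 48.4 in the other pairs within a group. The first principal component of log2 CPM held 60.5% of the variance and separated the surfaces: TH libraries lay at −16.3, −22.2 and −21.9, and THCaP libraries at 19.3, 35.9 and 5.17 for replicates 1, 2 and 3. THCaP replicate 3 was therefore the THCaP library nearest to TH. On the second component (13.7%) TH replicate 1 stood apart at 21.9, with the other libraries between −9.61 and −0.552.

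Among called genes with a mean of at least 10 CPM and no overlap between the surfaces, the largest decreases on THCaP were in Acod1, Ccl5 and Ptgs2. Acod1, which makes itaconate, fell 5.68-fold, from 38.7 ± 5.42 CPM to 6.82 ± 1.84 CPM (mean ± SD, n = 3 per surface; log2 fold change −2.51, SE 0.19, edgeR adjusted p = 0.000449). Transcripts of the chemokine Ccl5 were 5.20-fold lower (−2.38, SE 0.17) and those of the prostaglandin synthase Ptgs2 3.80-fold lower (−1.92, SE 0.21). The largest increases among such genes were smaller. Il1rl1, the receptor of interleukin-33, rose 2.34-fold from 9.75 ± 1.74 CPM to 22.8 ± 7.91 CPM (log2 fold change 1.22, SE 0.24, edgeR adjusted p = 0.0096). The metallothionein Mt2 rose 2.30-fold (log2 SE 0.14), the thymidylate synthase gene Tyms 2.27-fold (1.18, SE 0.23) and the fractalkine receptor Cx3cr1 2.27-fold (1.18, SE 0.21). On GRCm38, Acod1 lies on chromosome 14 at 103046977 to 103056573, Ccl5 on chromosome 11 at 83525778 to 83530518, Il1rl1 on chromosome 1 at 40429570 to 40465415 and Mt2 on chromosome 8 at 94172664 to 94173568, all protein coding. Values rest on the reads that the authors counted per gene.

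The next largest decreases, in order, were in the interferon-induced Ifi44l, the G protein regulator Rgs16, the co-stimulatory receptor Cd40 and Nos2, the inducible nitric oxide synthase (3.19-fold; −1.67, SE 0.19). The kinase Plk2, the interferon-induced Irf7, the hyaluronan receptor Layn, the interferon-induced Slfn2 and the immune checkpoint ligand Cd274 followed, with log2 fold changes from −1.75 for Ifi44l to −1.41 for Cd274. The other genes with the largest increases were the replication genes Pclaf, Pole and Mcm2, the histone-binding Hirip3, the chemokine Cxcl14, the mitochondrial cysteinyl-tRNA synthetase Cars2, Lrrc14 and the fatty acid translocase Cd36, with log2 fold changes from 1.12 for Cxcl14 to 0.99 for Cd36. As the naming rule required, each of these 24 genes was higher, or lower, in all 3 THCaP libraries than in any TH library.

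**Figure D1:**
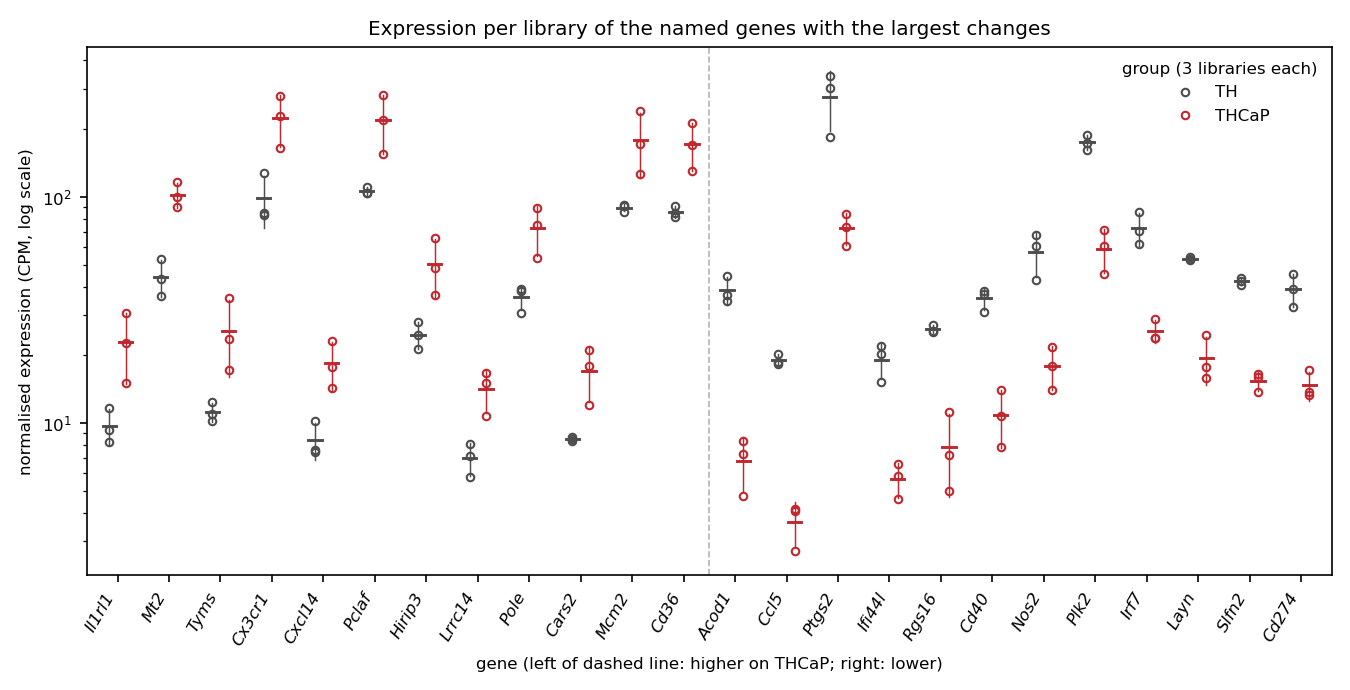
Expression of the 12 genes with the largest increase (left of the dashed line) and the 12 with the largest decrease (right) under the naming rule, in CPM on a log axis; circles are libraries, horizontal bars group means and vertical bars ± SD (n = 3). The rule took only genes for which the groups do not overlap. Acod1 falls from a mean of 38.7 to 6.82 CPM and Mt2 rises from 44.4 to 102 CPM.

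In all, edgeR called 1333 genes higher and 1376 genes lower on THCaP, 23.6% of those tested. A change of at least 2-fold was rarer, with 45 genes higher and 143 lower, and the median absolute log2 fold change of called genes was 0.49. In 2659 of the 2709 called genes the libraries of the surfaces did not overlap, and 43.4% of all tested genes were separated in this way. By chance 10% of genes would be separated on average over the divisions into 3 and 3. Genes move together and are not replicates, so the share in 1 division can lie far from this average. The balance of directions depended on scaling: with library totals in place of TMM factors 1904 genes were higher and 1063 lower, and with FPKM 1762 were higher and 964 lower. The counts also depended on single libraries: they were 294 higher and 506 lower without TH replicate 2, 294 and 490 without TH replicate 3, 291 and 465 without THCaP replicate 1, 734 and 937 without THCaP replicate 2, and 2145 and 2020 without THCaP replicate 3. The 188 genes changed at least 2-fold became 118 without TH replicate 2, 117 without TH replicate 3, 112 without THCaP replicate 2 and 385 without THCaP replicate 3, and 91 with a stricter filter. Of the 110 named genes that were called, 66 kept their call in every alternative that tested them, the fold tested against 1.2 left aside. That stricter test kept 532 of the 2709 calls and was not tallied for the named genes. Il1rl1, Tyms, Rrm2, Eno2 and Osm kept it in 17 of 18. Without each library in turn, 71 of the 110 kept their call. The other 39 include Tnf, Vegfa and Acp5, and where such a gene is described the libraries concerned are given with it.

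Of 18 tested genes of the pro-inflammatory list, 9 fell, 0 rose and 9 were not called. The number lower was 11 when adjusted over the list alone. The median log2 fold change was −0.81 and camera's adjusted p was 5.8e-07, or adjusted p = 0.121 with an estimated correlation. Beside Acod1, Ptgs2 and Nos2, Cd40 was 3.27-fold lower. Tnf fell by only 0.47 on the log2 scale (SE 0.10, from 124 ± 4.39 to 89.6 ± 11.3 CPM, n = 3 each; edgeR adjusted p = 0.0118), a call that was lost without TH replicate 2 (0.0529), TH replicate 3 (0.0531) or THCaP replicate 1 (0.0605). Il1b was near the detection limit on both surfaces, at 0.573 ± 0.27 CPM on TH and 0.399 ± 0.0917 CPM on THCaP (edgeR adjusted p = 0.406), and Il6 did not pass the filter, with 4 counts summed over the TH libraries and 1 over the THCaP libraries. Of 16 chemokine and chemokine receptor genes, 9 fell and 2 rose (9 and 3 adjusted over the list alone), with a median of −0.89 (camera adjusted p = 0.000531; adjusted p = 0.343 with an estimated correlation). Ccl5 and Ccl4 (−1.22, SE 0.16) fell, while Cx3cr1 and Cxcl14 rose.

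Genes of Toll-like receptor and NF-κB signalling fell in part. Of 45 tested genes, 16 fell and 1 rose (18 and 1 adjusted over the list alone), with a median of −0.14 (camera adjusted p = 8.9e-06; adjusted p = 0.331 with an estimated correlation). The signalling adaptors and NF-κB-induced regulators Traf1 (−1.17, SE 0.12), Bcl3 (−1.15, SE 0.11), Irak2 (−1.11, SE 0.12) and Birc3 (−0.90, SE 0.10) showed the largest decreases among members with at least 5 CPM. Of 39 tested genes of the interferon response, 23 were lower, 0 were higher and 16 were not called (24 lower adjusted over the list alone), with a median of −0.60 (camera adjusted p = 1.1e-12; adjusted p = 0.343 with an estimated correlation). Rsad2, an antiviral enzyme, was 4.08-fold lower, Ifi44l 3.36-fold and the transcription factor Irf7 2.85-fold. The relative mean log2 expression of this list, with the mean of the 6 libraries set to 0, was 0.356, 0.473 and 0.176 in TH replicates 1 to 3 and −0.357, −0.162 and −0.487 in THCaP replicates 1 to 3. Of 19 genes of antigen presentation and dendritic cells, 10 fell and 0 rose (10 adjusted over the list alone). Their median was −0.49 (camera adjusted p = 9.4e-05, or adjusted p = 0.343 with an estimated correlation). Those that fell included the maturation marker Cd83 (−0.94, SE 0.17) and the class I genes H2-K1 (−0.61, SE 0.09) and H2-D1 (−0.61, SE 0.08), which are similar in sequence.

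Genes linked to alternative activation did not rise as a group. Of 18 tested, 5 fell and 0 rose, and 13 were not called (5 lower and 1 higher adjusted over the list alone). Il1rn, the interleukin-1 receptor antagonist, was 1.92-fold lower (−0.94, SE 0.19, edgeR adjusted p = 0.0101), and Myc (−1.36, SE 0.25), Stab1 (−1.28, SE 0.25) and Flrt2 (−0.91, SE 0.16) fell. Camera placed the list below other genes (median −0.26, adjusted p = 0.034, or adjusted p = 0.457 with an estimated correlation). That call was lost without TH replicate 1 (median −0.15, adjusted p = 0.328) or THCaP replicate 2 (median −0.044, adjusted p = 0.097), and the median was −0.42 without THCaP replicate 3. It was also lost in 6 other alternatives (adjusted p up to 0.407), among them fry (adjusted p = 0.124). Arg1 (7 counts over the TH libraries, 8 over the THCaP libraries), Il10 (3 and 9) and Mrc1 (21 and 39) were too low to test.

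Of 20 tested genes with roles in bone formation and vessel growth, 10 fell and 1 rose (12 and 1 adjusted over the list alone). Their median was −0.46 (camera adjusted p = 2.1e-05, or adjusted p = 0.343 with an estimated correlation). Spp1, which encodes osteopontin, fell 1.93-fold from 1372 ± 21.2 CPM to 712 ± 55.9 CPM (n = 3 each; log2 fold change −0.94, SE 0.08, edgeR adjusted p = 0.000708). Hbegf fell 3.99-fold, and the interleukin-6 family cytokines Osm (−0.88, SE 0.16) and Lif fell. Vegfa was 1.57-fold lower (−0.65, SE 0.14, edgeR adjusted p = 0.0139; 0.0546 without TH replicate 3 and 0.0526 without THCaP replicate 1). Tgfb1 stood at 127 ± 10.5 CPM on TH and 132 ± 14.7 CPM on THCaP (0.05, SE 0.10, edgeR adjusted p = 0.738), and Bmp2 was below the filter with 8 counts over the TH and 1 over the THCaP libraries. In the osteoclast list 13 of 32 genes fell and 0 rose (14 and 2 adjusted over the list alone). The median was −0.19 (camera adjusted p = 0.000531, or adjusted p = 0.343 with an estimated correlation). Without TH replicate 1 the median of this list was −0.31 (camera adjusted p = 0.00826). Its members Fosl1 (−1.11, SE 0.11), Fosl2 (−0.77, SE 0.11) and Bcl6 (−0.77, SE 0.13), transcription factors, fell, as did Acp5, tartrate-resistant acid phosphatase (−1.06, SE 0.24, edgeR adjusted p = 0.0169; 0.0516 without TH replicate 1 and 0.0602 without TH replicate 3). Ctsk was not called, at 1.08 ± 0.461 CPM on TH and 0.969 ± 0.171 CPM on THCaP (edgeR adjusted p = 0.798).

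Matrix and protease genes fell in 13 of 24 cases and rose in 0 (16 lower adjusted over the list alone). The median was −0.43 (camera adjusted p = 5.5e-07, or adjusted p = 0.215 with an estimated correlation). The gelatinase gene Mmp9 was 3.69-fold lower, at 5.31 ± 0.703 CPM on TH and 1.43 ± 0.56 CPM on THCaP (n = 3 each). The protease Adam8 was 1.87-fold lower and the urokinase gene Plau 1.78-fold.

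Of 76 tested cell cycle genes, 60 were higher, 1 was lower and 15 were not called (68 higher and 1 lower adjusted over the list alone), with a median of 0.54 (camera adjusted p = 3.1e-21; adjusted p = 0.343 with an estimated correlation). The replication genes Tyms (1.18, SE 0.23), Pole (1.02, SE 0.17), Mcm2 (0.99, SE 0.19) and Rrm2 (0.99, SE 0.20) led the members with at least 5 CPM. The only member that fell was the D-type cyclin Ccnd2 (−0.86, SE 0.12), named after its value was seen. The relative mean log2 expression of the list was −0.362, −0.238 and −0.222 in TH replicates 1 to 3 and 0.283, 0.502 and 0.036 in THCaP replicates 1 to 3, so that the increase over TH was smallest in THCaP replicate 3. Of 35 immediate early genes and feedback regulators of MAP kinase signalling, 21 fell, 0 rose and 14 were not called (26 lower adjusted over the list alone). Their median was −0.57 (camera adjusted p = 1.6e-12, or adjusted p = 0.343 with an estimated correlation), and those that fell included Etv4 (−1.38, SE 0.20), Dusp5 (−1.31, SE 0.20) and Phlda1 (−1.31, SE 0.11). Of 43 genes of the p53 and apoptosis list 15 fell and 5 rose (19 and 6 adjusted over the list alone). Their median was −0.25 (camera adjusted p = 0.00501, or adjusted p = 0.215 with an estimated correlation). Without THCaP replicate 2 it was −0.14 (camera adjusted p = 0.000961). Without genes shared with other lists the median of this list was −0.058 (camera adjusted p = 0.0317). Its members with the largest changes at 5 CPM or more were the kinase Plk2 (2.94-fold lower), Gadd45b (1.88-fold lower) and the inhibitors of cell death Cflar (2.20-fold lower) and Birc3 (1.86-fold lower).

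Cytosolic ribosomal protein genes lay slightly lower on THCaP, by similar amounts across genes (quartiles −0.28 and −0.22) but not across libraries. All 45 tested had negative log2 fold changes, 14 fell and 0 rose (34 lower adjusted over the list alone), with a median of −0.25 (camera adjusted p = 7.4e-10; adjusted p = 0.456 with an estimated correlation; fry adjusted p = 0.0644). Rplp2 (−0.33, SE 0.09) and Rpl30 (−0.31, SE 0.09) were among those that fell. Each lost its call without TH replicate 2, TH replicate 3 or THCaP replicate 1, and Rplp2 also without THCaP replicate 2, with adjusted p up to 0.106 for Rplp2 and 0.123 for Rpl30. The list stood highest in TH replicate 1, at 0.265 in relative mean log2 expression against 0.0218 and 0.0746 in the other TH libraries and −0.133, −0.166 and −0.063 in THCaP replicates 1 to 3. With library totals in place of TMM factors, 0 of 54 genes with Rpl as the letters before the first digit of the symbol were called in place of 15. Among the 44 with Rps there, 2 were called in place of 10. These groups, formed by symbol alone, are not the same as the list. Their medians were −0.19 and −0.17 in place of −0.25 and −0.22, while the median of all tested genes was 0.059 in place of 0.0064. Rpl30 (adjusted p = 0.0596) was among those that lost the call, and so did Rplp2 (adjusted p = 0.051), which is in neither group.

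**Figure D2:**
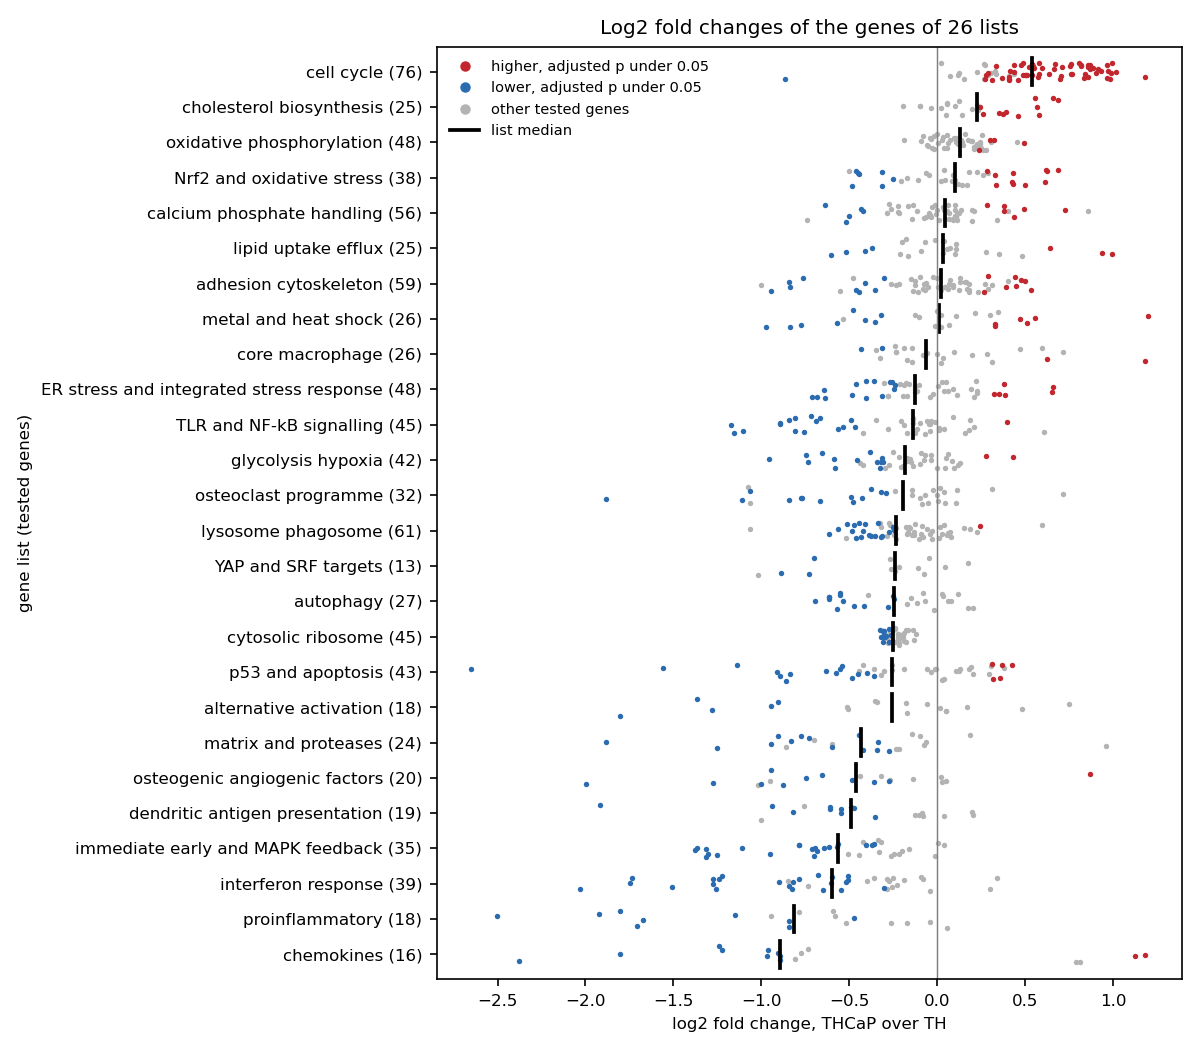
Log2 fold changes (THCaP over TH) of the tested genes of 26 lists, with the number of genes in brackets; each point is a gene, coloured by its edgeR call at an adjusted p under 0.05, and the black bar is the list median. The median of cell cycle genes is 0.54 (60 of 76 called higher, 1 lower), and the medians of chemokine, pro-inflammatory, interferon and immediate early genes are from −0.89 to −0.57 (2 of 16 chemokine and chemokine receptor genes called higher).

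Metabolic lists moved in different directions. Of 25 genes of cholesterol biosynthesis 11 were higher and 0 lower (12 higher adjusted over the list alone). The median was 0.23 (camera adjusted p = 0.000345, or adjusted p = 0.362 with an estimated correlation). The mevalonate kinase gene Mvk was 1.58-fold higher (0.66, SE 0.12). Hsd17b7 was 1.49-fold higher (0.58, SE 0.12), a call lost without TH replicate 2 (adjusted p = 0.0516). Oxidative phosphorylation genes lay slightly higher (median 0.13, camera adjusted p = 0.00315, or adjusted p = 0.694 with an estimated correlation). Camera lost the call without THCaP replicate 2 (median 0.066, adjusted p = 0.0612), and fry gave an adjusted p of 0.282. In this list 4 of 48 genes were called higher and 0 lower, and 0 when adjusted over the list alone. Those 4, Ndufa4 (0.49), Fh1 (0.32), Ndufa9 (0.30) and Ndufv2 (0.24), each lost their call without TH replicate 2, TH replicate 3, THCaP replicate 1 or THCaP replicate 2, with adjusted p up to 0.166. Ndufa4 (0.0687), Fh1 (0.0547) and Ndufa9 (0.0667) lost it also without TH replicate 1. Glycolysis and hypoxia genes fell in 13 of 42 cases and rose in 2 (15 and 2 adjusted over the list alone). The median was −0.18 (camera adjusted p = 0.000724, or adjusted p = 0.456 with an estimated correlation). Fry gave an adjusted p of 0.147. Without THCaP replicate 2 the median was −0.12 (camera adjusted p = 0.0071). The enolase gene Eno2 was 1.94-fold lower (−0.96, SE 0.19). In lipid uptake and efflux, 3 genes rose and 4 fell of 25 (the same numbers adjusted over the list alone), with a median of 0.03 (camera adjusted p = 0.973). Cd36 (0.99, SE 0.15) and the lysophospholipid acyltransferase Lpcat2 (0.64, SE 0.11) rose, and the lipase Pnpla2 (−0.52, SE 0.10) fell.

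Of 61 lysosome and phagosome genes 19 fell, 1 rose and 41 were not called (25 and 2 adjusted over the list alone). The median was −0.23 (camera adjusted p = 6.2e-06, or adjusted p = 0.367 with an estimated correlation), and the genes that fell included the glycosidases Gla (−0.56, SE 0.09) and Neu1 (−0.48, SE 0.08). Of 27 autophagy genes 13 fell and 0 rose (13 adjusted over the list alone), with a median of −0.25 (camera adjusted p = 0.000345, or adjusted p = 0.343 with an estimated correlation). They included the cargo receptor Sqstm1 (−0.61, SE 0.09) and Gabarapl1 (−0.61, SE 0.09). Genes of endoplasmic reticulum stress and the integrated stress response split: 14 of 48 fell and 6 rose (14 and 6 adjusted over the list alone; median −0.13). The stress factor Ddit3 (−0.71, SE 0.11) and the chaperone Hspa5 (−0.69, SE 0.10) fell. The amino acid transporter Slc7a5 (0.66, SE 0.15) and the serine pathway enzyme Shmt2 (0.65, SE 0.16) rose. Both lost their calls without TH replicate 2 or TH replicate 3 (adjusted p up to 0.0777), and Shmt2 also without THCaP replicate 1 (0.0551). Camera's adjusted p for this list was 0.022, or adjusted p = 0.456 with an estimated correlation. It was 0.0605 without TH replicate 3, 0.359 without THCaP replicate 3 (median −0.064), 0.0614 without genes shared with other lists and 0.124 with fry.

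Calcium and phosphate handling genes, which the coating's composition brings into question, did not move as a group. Of 56 tested, 6 rose and 5 fell (the same numbers adjusted over the list alone), with a median of 0.04 (camera adjusted p = 0.817). The mitochondrial sodium-calcium exchanger Slc8b1 (−0.50, SE 0.08), the plasma membrane calcium pump Atp2b1 (−0.52, SE 0.12) and the channel Trpm4 (−0.64, SE 0.14) fell, and the nucleotide receptor P2ry6 (0.73, SE 0.19) rose. Atp2b1, Trpm4 and P2ry6 lost their calls without TH replicate 2 or THCaP replicate 1, Atp2b1 and P2ry6 also without TH replicate 3 and P2ry6 without THCaP replicate 2 (adjusted p up to 0.0994). The phosphate transporter Slc20a1 stood at 140 ± 9.21 CPM on TH and 121 ± 7.24 CPM on THCaP (−0.22, SE 0.08, edgeR adjusted p = 0.0866). Adhesion and cytoskeleton genes went both ways, with 8 of 59 higher and 9 lower (11 and 12 adjusted over the list alone; camera adjusted p = 0.973). Their median was 0.02, their mean −0.04 and camera's direction upward against fry's downward, so that no direction is given. The GTPase Rhoc (−0.95, SE 0.11) and the adhesion molecule Icam1 (−0.76, SE 0.09) fell, and the actin-binding proteins Flna (0.54, SE 0.14) and Tagln2 (0.50, SE 0.12) rose, although both lost their calls without TH replicate 1, 2 or 3 or THCaP replicate 1 (adjusted p up to 0.0833). Of 13 targets of the mechanosensitive factors YAP and SRF, 3 fell and 0 rose (3 adjusted over the list alone), among them the immediate early gene Egr1 (−0.70, SE 0.12). The median was −0.24 (camera adjusted p = 0.0179, or adjusted p = 0.39 with an estimated correlation). This call was lost with fry (adjusted p = 0.0644), with offsets for GC content and gene length (0.0589) and without genes shared with other lists (0.226).

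Oxidative stress genes regulated by Nrf2 split into 11 higher and 7 lower of 38 (12 and 7 adjusted over the list alone). The median was 0.10 (camera adjusted p = 0.232, but 0.0497 without THCaP replicate 3). Gpx1 (0.62, SE 0.14), Gsr (0.62, SE 0.14) and Pgd (0.69, SE 0.17), which handle peroxide, glutathione and NADPH, rose. All 3 lost their calls without TH replicate 2 or THCaP replicate 1, and Gsr and Pgd also without TH replicate 3 (adjusted p up to 0.0818). In the list of metal-responsive and heat shock genes 6 rose and 8 fell of 26 (7 and 8 adjusted over the list alone). The median was 0.01, the mean −0.04 and camera's direction down (adjusted p = 0.817). Mt2 rose and the metal transporter Slc11a2 fell (−0.84, SE 0.12).

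Genes of macrophage identity changed little as a group: of 26, 2 rose and 2 fell (6 and 6 adjusted over the list alone), with a median of −0.06, a mean of 0.06 and camera's direction down (adjusted p = 0.817). Cx3cr1 rose. The lysozyme gene Lyz2 rose (0.63, SE 0.16), a call lost without TH replicate 2, TH replicate 3 or THCaP replicate 1 (adjusted p up to 0.0904). The Fc receptor Fcgr2b fell (−0.43, SE 0.08, edgeR adjusted p = 0.00964; 0.05003 without THCaP replicate 1). Of 60 markers of stromal, endothelial, lymphoid and neutrophil cells in the table, 48 did not pass the filter, with at most 13 counts in any library. Among the 12 tested, the intermediate filament gene Vim, also expressed by macrophages, fell (−0.40, SE 0.11), a call lost without TH replicate 1, 2 or 3 or THCaP replicate 1 (adjusted p up to 0.0938). The granulocyte colony-stimulating factor receptor gene Csf3r rose (0.48, SE 0.15, edgeR adjusted p = 0.0469), a call lost without TH replicate 2 or 3 or THCaP replicate 1 or 3 (adjusted p up to 0.163). The other 10, among them Eng (adjusted p = 0.974) and Lck (−0.22, SE 0.19), were not called. Mitochondrially encoded genes were not analysed here.

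In total, 20 of the 26 lists passed camera's threshold, 3 upward and 17 downward. On the 10 ways to divide the 6 libraries into 3 and 3, camera also called up to 18 lists on a division that mixes the surfaces. Such a division still sets unequal numbers of TH and THCaP libraries against each other, so part of the surface difference stays in it. Fry called 14 of the 20 in 1 direction and its mixed test called 25 of 26 lists. With an estimated correlation 0 lists passed camera's threshold, 3 had an unadjusted p under 0.05, and the lowest adjusted p was 0.121, for the pro-inflammatory list. The estimated correlation was −0.028 for that list and −0.0025 for the p53 and apoptosis list, below the preset 0.01. A higher correlation therefore does not account for the loss of these calls. On the mean expression of a list per library, the lists described as rising or falling were separated between the surfaces with the smallest exact permutation p that 3 against 3 libraries allow, 0.1, except oxidative phosphorylation and endoplasmic reticulum stress (exact permutation p = 0.2 each).

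**Figure D3:**
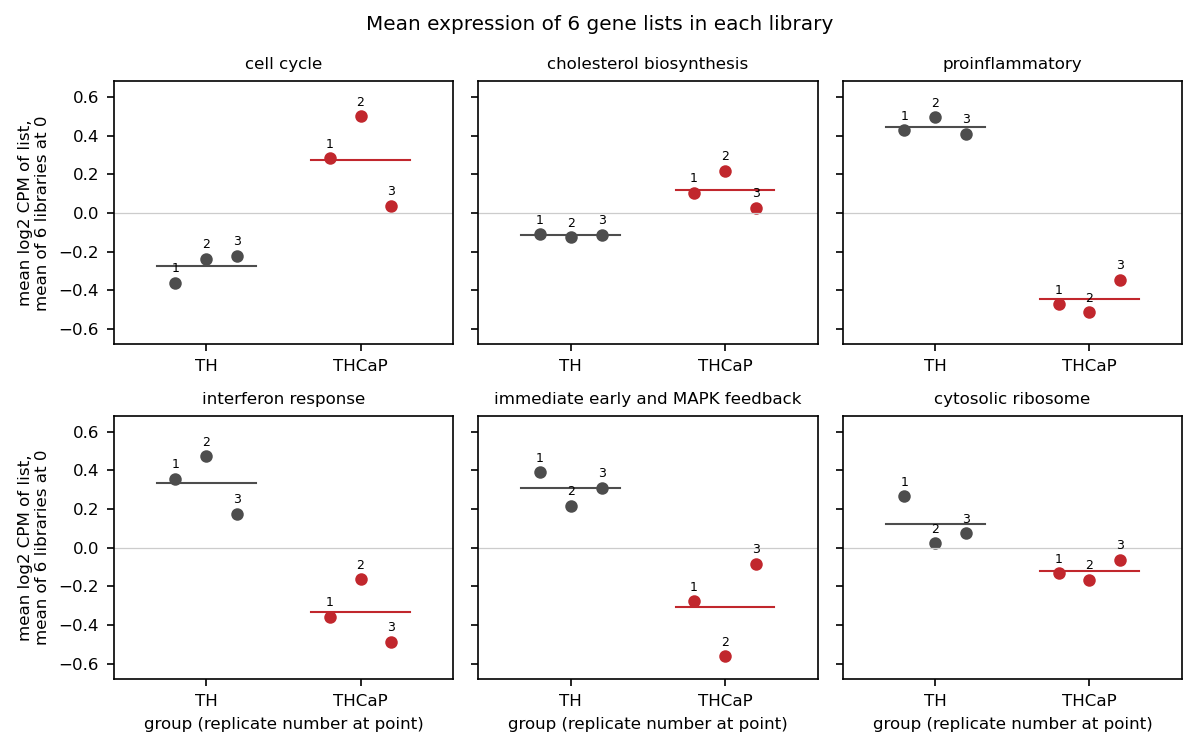
Mean log2 CPM of the tested genes of 6 lists in each library, with the mean of the 6 libraries set to 0; points are libraries, with the replicate number at each, and lines are group means (n = 3). The surfaces are separated in all 6 lists; within THCaP, replicate 3 is lowest for cell cycle genes (0.036, against 0.502 in replicate 2) and for interferon genes (−0.487, against −0.162 in replicate 2).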

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

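The offsets for GC content and gene length and the omission of both outlying libraries were chosen after seeing the data. No called gene changed sign in any alternative. DESeq2, limma-voom, RLE factors, library totals, no filter, the replicate block and both added alternatives left the counts of genes higher, lower and changed at least 2-fold within 1.5 times of 1333, 1376 and 188. Both outlying libraries left out gave 1641, 1885 and 174. With the stricter filter 91 genes changed at least 2-fold, although 9724 genes were still tested and 2647 called. Whether the other genes changed at least 2-fold lay below that filter was not tested. FPKM gave 41 such genes with a pseudocount of 1 and 84 with 0.1, with another test, filter and scaling, and the cause was not tested. Without a filter FPKM gave 766 higher, 528 lower and 40 changed at least 2-fold. Tested against a fold of 1.2, 181 genes were higher and 351 lower. Leaving out each library in turn gave 291 to 2145 genes higher, 465 to 2020 lower and 112 to 385 changed at least 2-fold. Fewer samples enter each of these fits, and why the counts differ between omissions was not tested.

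With an estimated correlation 0 of the lists passed. The number was 17 to 20 in the other camera alternatives and 14 with fry. FPKM without a filter, which takes in members of a list below the filter, moved 12 list medians by over 1.5 times. They became −0.10 for chemokines (in place of −0.89), −0.042 for antigen presentation (−0.49), −0.032 for bone and vessel factors (−0.46), −0.026 for matrix and proteases (−0.43), −0.30 for the pro-inflammatory list (−0.81), −0.25 for interferon (−0.60), −0.075 for p53 and apoptosis (−0.25), −0.020 for YAP and SRF targets (−0.24), −0.041 for the osteoclast list (−0.19), −0.074 for Toll-like receptor signalling (−0.14), −0.082 for endoplasmic reticulum stress (−0.13) and −0.0020 for alternative activation (−0.26). Camera kept all of these but alternative activation (adjusted p = 0.139) past its threshold. Counts without a filter gave −0.23 for matrix and proteases, −0.71 for bone and vessel factors and −0.022 for alternative activation. Up to 6 list medians moved as far in any other alternative, and the cause was not tested. Leaving out both outlying libraries gave −0.15 for cytosolic ribosomal protein genes (in place of −0.25), −0.36 for immediate early genes (−0.57) and −0.13 for lysosome and phagosome (−0.23). It gave −0.15 for autophagy (−0.25), −0.15 for p53 and apoptosis (−0.25) and −0.014 for alternative activation (−0.26). Without shared genes the median was −0.058 for p53 and apoptosis and −0.43 for the osteoclast list (−0.19). Sign changes concerned values near 0 that were not called in any alternative, and the cause was not tested. Eng changed from −0.0094 to 0.044 with library totals, 0.028 and 0.043 with FPKM at pseudocounts of 1 and 0.1, 0.028 with FPKM without a filter, 0.047 with GC and length offsets and 0.14 with both outlying libraries left out. It ranged from −0.12 to 0.088 with each library left out in turn. Over those omissions Ctsk ranged from −0.46 to 0.15 and Tgfb1 from −0.028 to 0.13. The median of the macrophage identity list was 0.00066 and 0.00067 with FPKM, 0.032 without shared genes and 0.060 with both outlying libraries left out, and ranged from −0.10 to 0.019 over the omissions. The metal and heat shock list had −0.0094 with GC and length offsets and −0.0047 with both outlying libraries left out, with −0.022 to 0.067 over the omissions. Lipid uptake and efflux ranged from −0.0017 to 0.072.

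The labels number the replicates 1 to 3 on both surfaces. Deviations from the group means correlated at −0.13, −0.19 and 0.19 across 9191 genes between libraries of the same number, and not every library correlated best with its own number. Deviations from a mean of 3 libraries depend on each other, so whether the numbers mark a shared experiment cannot be decided. The replicate block gave 1424 genes higher, 1457 lower and 210 changed at least 2-fold, and 19 lists, without that of endoplasmic reticulum stress (adjusted p = 0.0519). At this depth genes such as Il6, with at most 3 counts in a library, cannot show a difference.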

Other observations

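The tests of RNA mixing, of the growth state, of marker medians, of matched genes of limited length and of the correlation between THCaP replicates, the grouping of genes by symbol and the offsets for GC content and gene length were chosen after the results were seen. Genes were grouped by the letters that open their symbols, which gave 130 groups with at least 10 tested genes. Camera called 16 groups, 8 upward and 8 downward, and 0 with an estimated correlation (lowest adjusted p = 0.874). Nucleoporin genes (Nup), which build the nuclear pore, had 9 of 20 members higher and 0 lower (median 0.38; camera adjusted p = 0.000391); Nup85 (0.99, SE 0.22) and Nup155 (0.68, SE 0.13) rose most. The Mcm group had 8 of 10 higher and 0 lower (median 0.89), in part the genes of the cell cycle list. Splicing factors of the Srsf group had 3 of 10 higher and 0 lower (median 0.30; adjusted p = 0.0233), and small subunit proteins of the mitochondrial ribosome (Mrps) 4 of 29 higher and 0 lower (median 0.21; adjusted p = 0.016). Among the groups that fell were Tnfrsf receptors, with 6 of 16 lower and 0 higher (median −0.38; adjusted p = 0.00743), led by Tnfrsf9 (−1.31, SE 0.17), and Klf transcription factors, with 4 of 11 lower and 0 higher (median −0.29; adjusted p = 0.0233). All of these medians kept their sign with library totals and with RLE factors, but with library totals 7 Srsf, 6 Mrps, 12 Nup, 8 Mcm, 7 Tnfrsf and 4 Klf genes were called (with RLE factors 3, 4, 10, 8, 6 and 4). Single libraries were not left out for these groups, and the genes named here were chosen after their values were seen.

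The 6 libraries can be divided into 3 and 3 in 10 ways, too few for a share under 0.05, and in each of the 4 counts 1 of the 10 splits, the real one, was as large. The real split gave 1333 genes higher, 1376 lower and 188 changed at least 2-fold by edgeR, and the highest of the others 0 in each case. For lists past camera's threshold the real split gave 20 and the highest of the others 18. Every other split still sets unequal numbers of TH and THCaP libraries against each other, so part of the surface difference stays in it. Neither its lists nor its 0 genes therefore measure chance.

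The increase of cell cycle genes and the decrease of interferon and immediate early genes on THCaP were weighed against technical sources. After each library's trend on GC content and gene length was removed, the median of the 76 cell cycle genes was 0.55 (bootstrap 95% interval 0.46 to 0.67) in place of 0.54, and that of the 74 interferon and immediate early genes −0.56 (−0.66 to −0.41) in place of −0.57, which argues against such a bias. Both intervals resample genes, which are not independent, and hold no variation between libraries. Stromal, endothelial, lymphoid and neutrophil cells as a source of reads are argued against by the median CPM on THCaP over all markers of each list, tested or not, at most 0.034, although Vim stood at 1262 CPM and lower than on TH. The condition set beforehand, that no such marker is called higher, was not met: Csf3r, which macrophages also express, was called higher (14.9 CPM on TH, 20.8 on THCaP), but the 11 neutrophil markers sum to 21.6 CPM, so the others brought little, and other cell types were not covered. What stays open is whether the surfaces differed in cell density or growth state: within THCaP the SD of the cell cycle list's mean was 42.5% of the difference between the surfaces, and growth state and coating cannot be told apart in this design, as cell numbers may differ with the surface.

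The decrease of cytosolic ribosomal protein genes could come from a loss of short, abundant transcripts. After each library's trend on GC content and gene length was removed their median was −0.23 (bootstrap 95% interval over genes, which are not independent, −0.26 to −0.22) in place of −0.25, which argues against these trends as the whole cause. For the 20 other genes nearest in length and expression to each gene, the median of the median log2 fold changes was −0.081. These are 143 distinct genes, reused and longer (median 1184 against 867 bases), and resampling them gave −0.23 to 0.046, with −0.034 (−0.14 to 0.038) for the 29 no longer than 867 bases, so a loss of short, abundant transcripts and a change of ribosomal protein genes cannot be told apart. A biological difference between the surfaces also stays open, untested.

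If THCaP replicate 3, which lay nearest to the TH libraries, held RNA of TH cells, cell cycle genes and the genes that fell would need the same share. Taking THCaP replicate 1 as the unmixed level, the cell cycle genes need 50.1% of TH RNA (bootstrap 95% interval 45.1 to 55.0), and the intervals of 9 of the 17 lists that fell overlap this one (6 with the mean of THCaP replicates 1 and 2 as the level), some of them wide. The other 8 do not, among them the interferon list at −11.9% (−23.6 to −1.84), which lay lowest in THCaP replicate 3 (−0.487), where added TH RNA would raise it. These intervals resample genes, which are not independent, and hold no variation between libraries, so they may be too narrow and their overlap decides little. The unmixed level of replicate 3 is not known, so mixing of TH RNA, alone or with another difference, stays open. THCaP replicate 2 minus replicate 3 correlated at 0.50 (Pearson, across genes, which are not independent replicates) with THCaP replicate 1 minus the TH mean, which share no library; this is consistent with a graded difference along the axis that separates the surfaces, as a hypothesis, but mixing would give such a correlation too.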
